A study of Mus musculus with 9 samples.

How the data were processed

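Bulk RNA sequencing was analysed for 9 samples of aged C57BL/6 mice, all older than 18 months. There were 3 spleens of wild-type mice (numbers 1, 4 and 5), 4 spleens of plckGAPDH mice and 2 lymph nodes of plckGAPDH mice (animals 455 and 508). The plckGAPDH line carries a Gapdh transgene under the Lck promoter, which is active in the T cell lineage. Per the labels' protocols, total RNA was prepared from splenocytes, and libraries were made from 500 ng with a stranded total RNA kit and sequenced as 2 reads of 75 bases per fragment. The design text of the series names another sequencer than the protocol and speaks of triplicates, and the number of samples used here follows the sample labels. Animal 508 gave a spleen and a lymph node. The column of 1 plckGAPDH spleen gave no animal number, so that spleen entered the comparisons as a member of its group and is called the unnumbered spleen. The title of spleen 331 has no column of its own, and whether the 4 plckGAPDH spleens come from 4 animals was not settled. P-values measure the spread between these samples.

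The deposited table holds FPKM (fragments scaled by gene length and by all counted fragments) of 46517 genes with 2 decimals. Per the submitters' processing notes, STAR 2.4.0a, featureCounts of Subread 1.5.0-p3, RSEM and Bowtie2 2.2.6 were used with the mouse build mm10. Which of these tools made the FPKM and which annotation was used are not given in the sources used here. Because of that scaling, a gene that takes many fragments lowers every other gene of its library. Mitochondrial ribosomal RNA took between 23.8% of the estimated fragments (wild-type spleen 5) and 53.8% (wild-type spleen 4), and the FPKM columns summed to between 1028800 and 2667330.

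Because no counts were used, no count model was fitted, and the planned count tests were replaced by the planned test for normalized values. Depth was estimated from the low FPKM of genes with 1 annotated transcript, which fall on whole multiples of the value of 1 fragment. Between 79.9% and 86.1% of these values lay at whole fragments, within the rounding of the table and a small tolerance, against 22.0% to 27.1% by chance. The estimates ran from 23800000 fragments (plckGAPDH spleen 508) to 34400000 (plckGAPDH spleen 547), and on 3 simulated libraries the largest error was 1.84%. No pair of the 36 pairs of libraries shared more than 0.257% identical values among genes at 1 FPKM or more in both, so each library was counted as 1 sample.

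Spleens of the genotypes were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the prior variance, on the 7 spleens. Genes needed 1 FPKM in 3 spleens. Genes with a Benjamini-Hochberg false discovery rate (FDR) under 0.05 were called. A fold change on the log2(FPKM + 1) scale understates the change of low genes. Lymph nodes were compared with plckGAPDH spleens in a fit of 3 groups over all 9 samples, with 1 FPKM in 2 samples. On simulated spleens with the spread of the real genes and 12259 genes tested, none of 200 genes changed by 2 on the log2 scale was recovered. Of 200 genes changed by 3, 72.5% were recovered, with 6.45% false calls. Of 200 genes changed by 4, 87.5% were recovered, with 8.85% false calls. The changed genes were drawn only from genes with high means, and all genes varied independently. These rates therefore do not describe genes with low values or genes that move together.

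22 gene lists were fixed before the data were examined: follicular helper T cells, germinal centre B cells, plasma cells, pan-B and pan-T genes, regulatory T cells, CD8 T and NK cells, immature T cells, NF-kB targets, endothelium and angiogenesis, macrophages and monocytes, neutrophils, erythroid cells, megakaryocytes, dendritic cells, stromal and follicular dendritic cells, cell cycle, glycolysis without Gapdh, interferon response, immediate early and heat shock genes, exocrine pancreas and adipose tissue. They were tested with camera at a preset correlation of 0.01, two-sided, with estimated correlation and fry as alternatives. The list of adipose tissue had 0 members tested.

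Diversity of V genes was measured per library as the exponential of the Shannon entropy of FPKM shares within the Trbv, Trav, Ighv and Igkv families, called the effective number. It equals the number of V genes when all are used alike and is 1 when 1 V gene holds the whole family. Groups were compared with an exact two-sided permutation test over all 35 splits of the 7 spleens and Benjamini-Hochberg adjustment over the 4 families. Libraries with under 200 estimated fragments in a family were left out of tests of that family. V genes of a family resemble each other, so reads can be split among them and the name of a V gene carries that uncertainty.

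Genes were named by a rule fixed before the data were examined. It takes Gapdh, the 6 called genes with the largest rise and the 6 with the largest fall among genes with a mean of at least 2 on the log2 scale and no overlap between the groups, and of each list the member with the smallest p, or the first 2 where a member was called. Receptor segments, list members and genes with provisional names were left out of the first part. Coordinates are those of GENCODE M21 on GRCm38, the assembly of mm10, counted from 1. Alternatives tried were median-of-ratios scaling on 9013 genes, no filter, a filter of 5 FPKM, a pseudocount of 0.1, receptor genes left out, scaling to protein-coding genes, sample quality weights, other choices of samples and each library left out in turn. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.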

Results

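RNA of 9 samples was measured as FPKM: 3 wild-type spleens, 4 plckGAPDH spleens and 2 plckGAPDH lymph nodes. The labels describe the plckGAPDH mice as tumour-developing, and the comparison of the spleens asks how transgenic spleens of aged mice differ from wild-type spleens. Estimated depth was 23800000 to 34400000 fragments per library. The wild-type spleens differed from each other in content. Wild-type spleen 5 held 33216 FPKM of the beta-globin gene Hbb-bs, against 28.1 in wild-type spleen 1 and 0.170 in wild-type spleen 4. It also held 0.0900 FPKM of Xist, the RNA of the inactive X chromosome, against 31.2 to 59.7 in the other 8 libraries, and 30.5 FPKM of the Y-linked gene Eif2s3y, which was listed at 0 in the others. In wild-type spleen 4, the neutrophil gene S100a8 was at 1.37 FPKM, against 1162 in wild-type spleen 1.

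Gapdh, the gene of the transgene, lay higher in each of the 4 plckGAPDH spleens than in each wild-type spleen, but the difference did not pass the test. Its mean was 680 FPKM ± 247 (SD, n = 4) in plckGAPDH spleens and 328 ± 25.9 (SD, n = 3) in wild-type spleens. Spleens 343 and 508 held 430 and 505 FPKM, and spleen 547 and the unnumbered spleen 890 and 894. The log2 fold change was 0.97 (SE 0.49), with a limma FDR of 0.635. With sample quality weights, which gave wild-type spleen 1 a weight of 24.8 and the other spleens 0.296 to 2.04, the log2 fold change was 1.29 (limma FDR 0.0114); over the other alternatives the FDR ran from 0.308 to 0.9998. The lymph nodes held 312 (animal 508) and 554 FPKM (animal 455). Gapdh, the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, lies on chromosome 6, 125161715 to 125166467. Gapdh has many processed pseudogenes, and whether the transgene differs in sequence from the mouse gene is not given in the sources used here, so reads of the transgene and the endogenous gene were not separated.

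Most called changes between the spleens were losses of immunoglobulin V genes, the segments that encode the antigen-binding part of antibodies. Of 86 heavy-chain V genes tested, 58 fell and 0 rose, with a median log2 fold change of -2.84. Of 80 kappa V genes, 61 fell and 0 rose, with a median of -3.28. Of 59 T cell receptor V genes, 6 fell, with a median of -1.05. The median of the other genes was 0.03. A V gene abundant in only 1 plckGAPDH spleen could not reach the filter of 1 FPKM in 3 spleens through that spleen alone. Nor would a rise in 1 spleen be called, so the absence of rises carries little weight. Without a filter the medians were -1.96 for heavy-chain and -2.44 for kappa V genes. Without wild-type spleen 1, 4 or 5, fewer V genes reached the filter, and 32, 28 and 29 of 61 heavy-chain and 37, 34 and 35 of 58 kappa V genes fell. Without both 4 and 5, 3 of 43 and 6 of 34 fell, and without a filter 31 of 140 and 36 of 124. T cell receptor V genes that fell numbered 2, 0 and 0 without wild-type spleen 1, 4 or 5, and 23 with sample quality weights. Over all 12607 genes tested with limma, 26 were higher and 155 lower in plckGAPDH spleens at an FDR under 0.05, and 1116 had an unadjusted p under 0.05. The groups did not overlap in 916 genes (7.27%, against 5.71% by chance). The total count of called genes was 110, 90 and 72 without wild-type spleen 1, 4 or 5, 12 without both 4 and 5, and 1863 with sample quality weights. The 26 higher genes became 9 with median-of-ratios scaling, 7 and 5 without wild-type spleen 4 or 5, 81 without plckGAPDH spleen 343 and 42 without spleen 547.

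The most abundant V genes differed between the plckGAPDH spleens. In spleen 547, Ighv12-3 (chromosome 12, 114366521 to 114366954) made 98.8% of heavy-chain V gene FPKM and Igkv4-91 (chromosome 6, 68768555 to 68769103) 98.6% of kappa V gene FPKM. In spleen 343, Ighv3-6 (chromosome 12, 114288152 to 114288582) made 73.0% and Igkv5-39 (chromosome 6, 69900424 to 69900977) 86.8%. In the unnumbered spleen, Ighv1-72 (chromosome 12, 115757984 to 115758461) made 70.0% and Igkv9-124 (chromosome 6, 67942074 to 67942540) 61.1%. Spleen 508 held mostly lambda light chain RNA, with Iglv1 at 42593 FPKM and Igkc at 0.904% of light-chain constant FPKM. Its Ighv1-54 at 31.8% and Igkv4-63 at 58.7% were shares of only 672 heavy-chain and 1125 kappa V gene FPKM. Wild-type spleens had Ighv1-26 at 7.84% (spleen 4) and Ighv3-6 at 5.44% (spleen 5), while Ighv4-1 reached 34.6% in wild-type spleen 1. The most abundant kappa genes of the wild-type spleens were Igkv19-93 at 23.2% (spleen 1), Igkv6-15 at 8.55% (spleen 4) and Igkv10-96 at 5.49% (spleen 5). These shares rested on 3392 to 21443 estimated heavy-chain and 4764 to 34029 kappa fragments per spleen.

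The effective number of heavy-chain V genes was 4.87 ± 4.41 (SD, n = 4) in plckGAPDH spleens and 45.5 ± 23.9 (SD, n = 3) in wild-type spleens. For kappa V genes it was 3.27 ± 2.07 (SD, n = 4) against 43.4 ± 16.3 (SD, n = 3). In both families each plckGAPDH spleen lay below each wild-type spleen, which gave an exact permutation p of 0.0286, the smallest that 35 splits allow. The values of spleen 508, 11.3 and 5.71, describe only a small part of its antibody RNA. Its Ighv genes summed to 672 FPKM beside Ighg2c at 59425 FPKM, and its light chain RNA was mostly lambda. The adjusted exact p was 0.0571 in both, so neither passed the threshold of 0.05. For Trav genes, of the T cell receptor alpha chain, the means were 26.6 ± 27.2 (SD, n = 4) and 71.2 ± 6.98 (SD, n = 3), with an exact p of 0.0571 and an adjusted p of 0.0762. For Trbv genes, of the beta chain, they were 9.58 ± 6.77 (SD, n = 4) and 17.8 ± 0.885 (SD, n = 3), with an exact p of 0.114 and the same adjusted p. With any library left out, the 15 or 20 splits allowed no exact p under 0.0667.

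**Figure D1:**
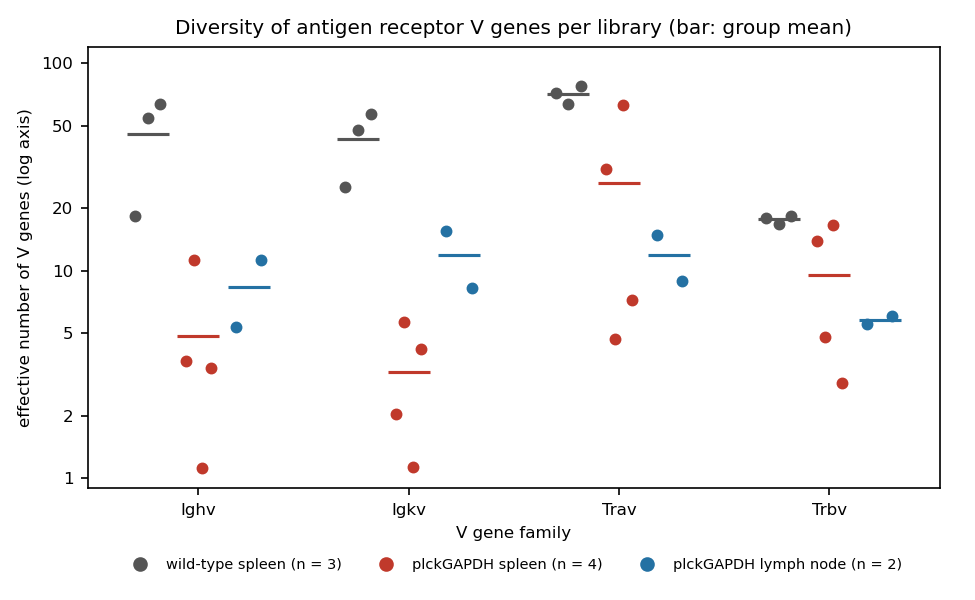
Effective number of V genes per library (points, log axis) and group mean (bar) in 4 receptor families, for 3 wild-type spleens, 4 plckGAPDH spleens and 2 plckGAPDH lymph nodes. Heavy-chain (Ighv) values of plckGAPDH spleens reached at most 11.3 and those of wild-type spleens at least 18.5, while Trbv values of both genotypes came close, at 16.7 and 16.8.

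T cell receptor genes were concentrated in some plckGAPDH libraries and not in others. In the unnumbered spleen, Trbv20 made 75.8% of Trbv FPKM and Trav10n 45.1% of Trav FPKM. In spleen 508, Trbv19 made 42.2% and Trav21-dv12 60.3%. In spleen 343, Trbv31 made 19.8%, and Trav6d-6 and Trav6-6, with equal values, were the most abundant Trav genes. In spleen 547, Trbv13-1 made 12.1% and Trav16d-dv11 4.73%. Among wild-type spleens, the most abundant genes were Trbv13-1 and Trbv15 at up to 10.9%, and Trav13d-1, Trav4-4-dv10 and Trav14d-1 at 3.45% to 6.79%. Trbv and Trav shares rested on 229 to 2345 estimated fragments per spleen.

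Heavy-chain constant regions, which set the antibody class, also differed from library to library. Ighg2c, of class IgG2c, made 98.0% of heavy-chain constant FPKM in plckGAPDH spleen 508, where it reached 59425 FPKM, with the lambda constant gene Iglc1 at 104354 FPKM. Ighm, of class IgM, made 94.0% in spleen 547 and 81.8% in the unnumbered spleen. In spleen 343, Ighm made 37.5%, Igha 22.3%, Ighg2b 21.3% and Ighg2c 16.7%. Ighm made 73.5% and 66.0% in wild-type spleens 1 and 5, and Ighg1 made 61.4% in wild-type spleen 4. No constant region gene was called between the groups.

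**Figure D2:**
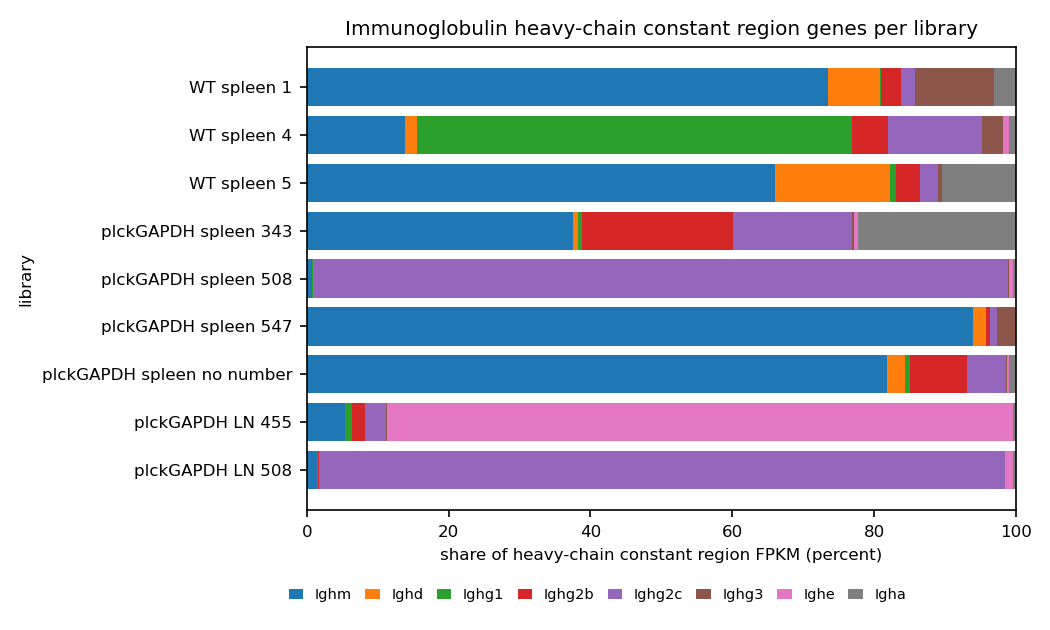
Share of 8 heavy-chain constant region genes in their summed FPKM (percent) per library, with the plckGAPDH spleen of unknown animal labelled no number. Ighg2c filled 98.0% in spleen 508 and 96.7% in lymph node 508, and Ighe 88.2% in lymph node 455.

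Among genes outside the receptor loci, 26 were higher and 30 lower in plckGAPDH spleens. The lower ones were 17 and 3 without wild-type spleen 1 or 5, 17 without plckGAPDH spleen 508 and 50 without the unnumbered spleen. The largest rises by the rule were those of Alpl, an alkaline phosphatase, at 16.9 FPKM ± 9.02 (SD, n = 4) against 1.08 ± 0.223 (SD, n = 3), with a log2 fold change of 2.92 (SE 0.48, limma FDR 0.00738), Parm1 at 2.85 (SE 0.54, limma FDR 0.0179) and Cpne8 at 2.66 (SE 0.47, limma FDR 0.0110). Timd2, Rnu1b6 and Lmo7 followed at 2.56, 2.55 and 2.12. Rnu1b6 is a U1 small nuclear RNA whose values were identical to those of the copies Gm24830 and Gm26232, so these were not told apart. The ligands Cd70 and Tnfsf9, which act on T cells, were also among the higher genes, at 1.74 (limma FDR 0.0486) and 1.64 (limma FDR 0.0486), and were chosen after their values were seen. The largest falls by the rule were those of Cnn3 at -3.43 (SE 0.56, limma FDR 0.00676), Cd55, a complement inhibitor, at -2.85 (SE 0.56, limma FDR 0.0234), BC094916 at -2.59, Ell3 at -2.52, Pydc3 at -2.47 and Arl4c at -2.46. BC094916 and Pydc3 belong to a family of similar interferon-inducible genes and are uncertain where reads were shared. These calls leaned on the receptor genes tested beside them: with those left out, 0 of 12360 genes were called with limma, 947 had an unadjusted p under 0.05, and the smallest FDR was 0.0664. Of the 17 called named genes, 3, 7, 11 and 10 stayed called without wild-type spleen 5, wild-type spleen 4, wild-type spleen 1 and plckGAPDH spleen 508. With limma, 0 stayed called without a filter on low values, 0 of 15 tested without wild-type spleens 4 and 5, 8 with median-of-ratios scaling and 9 with scaling to protein-coding genes.

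**Figure D3:**
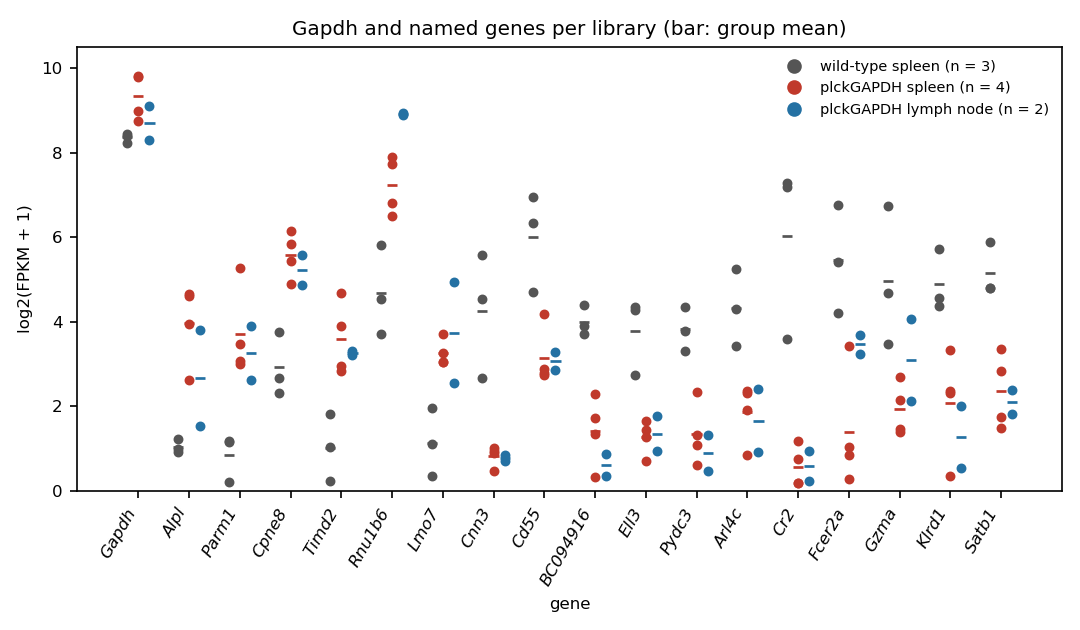
Expression of Gapdh and the 17 called named genes per library (points) and group mean (bar), as log2(FPKM + 1). Values of plckGAPDH spleens did not overlap those of wild-type spleens for the genes shown, Gapdh included, although Gapdh did not pass the test.

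Some genes of mature B cells fell. Cr2, the complement receptor CD21 of mature B cells, was at 0.562 FPKM ± 0.544 (SD, n = 4) in plckGAPDH spleens and 104 ± 80.5 (SD, n = 3) in wild-type spleens, a log2 fold change of -5.44 (SE 0.75, limma FDR 0.00169). Fcer2a, the IgE receptor CD23, fell by 4.05 on the log2 scale (SE 0.73, limma FDR 0.0136). Of the 13 pan-B genes, 12 had negative and 1 had positive fold changes; 2 fell over all genes tested and 3 adjusted over the list alone, the third being Ebf1 at -1.92. The other 10 lay between -1.68 (Bank1) and 0.17 (Cd22). The list as a whole was lower, with a median of -0.39 (camera FDR 0.000597, adjusted p = 0.669 with an estimated correlation). The median was -0.15 without wild-type spleen 1, -1.14 without wild-type spleen 4, -0.68 without plckGAPDH spleen 343, -0.59 without spleen 547 and -1.17 with sample quality weights.

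Genes of cytotoxic and natural killer cells were called lower as a list, but the sign of the median turned in some fits. Gzma, a granzyme, fell by 3.04 (SE 0.65, limma FDR 0.0404) and Klrd1, the NK receptor CD94, by 2.80 (SE 0.62, limma FDR 0.0486). Of the 15 members tested, 13 had negative and 2 positive fold changes; 2 fell over all genes and 5 adjusted over the list alone. The list's median was -0.80 (camera FDR 0.000120, adjusted p = 0.669 with an estimated correlation, 0.0538 without wild-type spleen 4). The median was -0.35 without wild-type spleen 4, -1.24 without plckGAPDH spleen 343, -1.48 without the unnumbered spleen, 0.09 without plckGAPDH spleen 508 (camera FDR 0.0124) and 0.43 with sample quality weights (0.555), while the test stayed on the lower side. All 15 pan-T genes had negative fold changes, none of them called, with a median of -0.69 (camera FDR 0.000597, adjusted p = 0.669 with an estimated correlation, 0.0593 without wild-type spleen 4). The median was -0.43 without spleen 508 and -1.29 without the unnumbered spleen. With sample quality weights the direction turned, with a median of 0.22 (camera FDR 0.348). Of the 9 immature T cell genes, only 3 were tested, so the list result does not describe the other members. Satb1, a chromatin organiser of thymocytes, fell by 2.80 (SE 0.51, limma FDR 0.0137), and Ccr9 was at -1.02. The median of the tested genes was -1.02 (camera FDR 0.00123, adjusted p = 0.669 with an estimated correlation, 0.0963 with sample quality weights). Of the tested genes, 2 fell adjusted over the list alone.

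Proliferation genes lay higher in some plckGAPDH spleens. All 21 cell cycle genes were above every wild-type spleen in spleen 547 and in the unnumbered spleen, 15 in spleen 508 and 7 in spleen 343. Of them, 5 did not overlap between the groups (23.8%, against 7.27% of all genes tested). Genes of a list can move together, so these are not 5 separate events. Over the lists this share ran from 0% (as for plasma cells) to 33.3% (dendritic cells and immature T cells). All 21 cell cycle genes had positive fold changes, with a median of 1.13 (camera FDR 3.61e-12, adjusted p = 0.669 with an estimated correlation). None was called over all genes, and 4 rose adjusted over the list alone. Mki67, a marker of cycling cells, was at 71.4 FPKM ± 52.6 (SD, n = 4) against 6.37 to 22.8 in wild-type spleens, a log2 fold change of 2.07 (SE 0.58, limma FDR 0.166), and reached 146 FPKM in spleen 547. Of 16 other glycolysis genes, 13 had positive fold changes and none was called, over all genes or adjusted over the list alone. Their median was 0.50 (camera FDR 0.00477, adjusted p = 0.669 with an estimated correlation) and 0.23 without the unnumbered spleen (0.0490), and Pkm, a pyruvate kinase, was at 228 FPKM against 92.2 (limma FDR 0.416).

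Plasma cell genes and neutrophil genes were called as lists, but each call rested on few libraries. The 12 plasma cell genes had a median of 0.87 (camera FDR 0.00357, adjusted p = 0.669 with an estimated correlation), none was called, and without spleen 508 the median was 0.32 and the adjusted p 0.940, without wild-type spleen 4 the median was 0.55, without spleen 343 it was 1.40, and the adjusted p was 0.294 with sample quality weights. Prdm1, a regulator of plasma cells, was at 1.29 (SE 0.48, limma FDR 0.385), and Jchain reached 3472 FPKM in spleen 508 against 9.21 to 37.4 in the other plckGAPDH spleens and 132 to 220 in wild-type spleens. All 13 neutrophil genes had positive fold changes, with a median of 1.18 (camera FDR 0.00387, adjusted p = 0.669 with an estimated correlation). That call was lost without wild-type spleen 4 (median 0.41, adjusted p = 0.872) or plckGAPDH spleen 508 (0.0616), while the median was 3.16 without wild-type spleen 1 (8.78e-19), and with wild-type spleens 4 and 5 both left out the median was -1.37 (1.04e-10). With sample quality weights it was -1.31 (camera FDR 0.00421). Lcn2 had the smallest p of the list, at 2.21 (SE 1.12, limma FDR 0.643).

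Dendritic cell and interferon-response genes were lower as lists. All 9 dendritic cell genes had negative fold changes, with a median of -0.78 (camera FDR 0.000163, adjusted p = 0.669 with an estimated correlation); none was called over all genes, and 3 fell adjusted over the list alone. Clec9a, a receptor of cross-presenting dendritic cells, was at -1.22 (SE 0.36, limma FDR 0.189). Of 14 interferon genes, 11 had negative fold changes, with a median of -0.81 (camera FDR 0.00232, adjusted p = 0.669 with an estimated correlation, 0.175 without wild-type spleen 4, and a median of -0.45 without wild-type spleen 5), and 1 fell adjusted over the list alone. With sample quality weights the interferon median was 0.36 (camera FDR 0.127). Ifit3 was at -2.10 (SE 0.57, limma FDR 0.141).

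The other lists were not called, which included follicular helper T cells and NF-kB targets. The 13 follicular helper genes had a median of -0.02 (camera FDR 0.919), which became 1.02 with sample quality weights (0.0306), and Cxcr5, the receptor that guides cells to follicles, was at -1.90 (SE 0.62, limma FDR 0.259). The 11 germinal centre B cell genes had a median of 0.71 (camera FDR 0.104), with FDRs of 0.000269 and 0.000175 without wild-type spleen 4 or plckGAPDH spleen 547 and 0.00284 with sample quality weights, and Gcsam was at -1.11 (limma FDR 0.286). Without wild-type spleen 1 the germinal centre median was 0.37 (camera FDR 0.622). The 17 NF-kB targets had a median of 0.17 (camera FDR 0.444, 0.0479 with sample quality weights), and Tnfaip3 was at 0.71 (limma FDR 0.732). The NF-kB median was -0.12 without wild-type spleen 4, -0.09 without the unnumbered spleen and 0.49 without plckGAPDH spleen 508 (camera FDR 0.0551), while the test stayed on the higher side. Regulatory T cell genes had a median of -0.21 (camera FDR 0.439, 0.0252 without wild-type spleen 5), with Il2ra at -1.25 (limma FDR 0.106), the only member that fell adjusted over the list alone. Medians were -0.33 for endothelium (camera FDR 0.153, 0.0238 without wild-type spleen 4; Pecam1 at -0.90), -0.45 for macrophages (0.238, 3.49e-06 without wild-type spleen 1; Spic at -0.89), -0.13 for stroma (0.614; Clu at -1.29) and 0.63 for immediate early genes (0.471; Jun at 1.46). Beside wild-type spleen 5, medians were 0.16 for erythroid cells (0.3995, 3.51e-06 without that spleen; Ermap at 1.17), 0.03 for megakaryocytes (0.956, with a mean of -0.14, and 0.0102 without it; Ppbp at -0.80) and -0.66 for exocrine pancreas (0.318, 9.87e-05 without it; Amy2a5 at -1.22). With 1 library left out, medians ran from -0.68 to 0.56 for follicular helper T cells, -1.05 to 0.57 for regulatory T cells, -0.65 to -0.15 for endothelium, -0.99 to 0.54 for macrophages, -0.42 to 0.25 for stroma, -0.03 to 0.89 for immediate early genes, -1.02 to 2.69 for erythroid cells, -0.72 to 0.92 for megakaryocytes and -1.74 to -0.25 for exocrine pancreas. In these lists, no member other than Il2ra was called adjusted over the list alone.

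**Figure D4:**
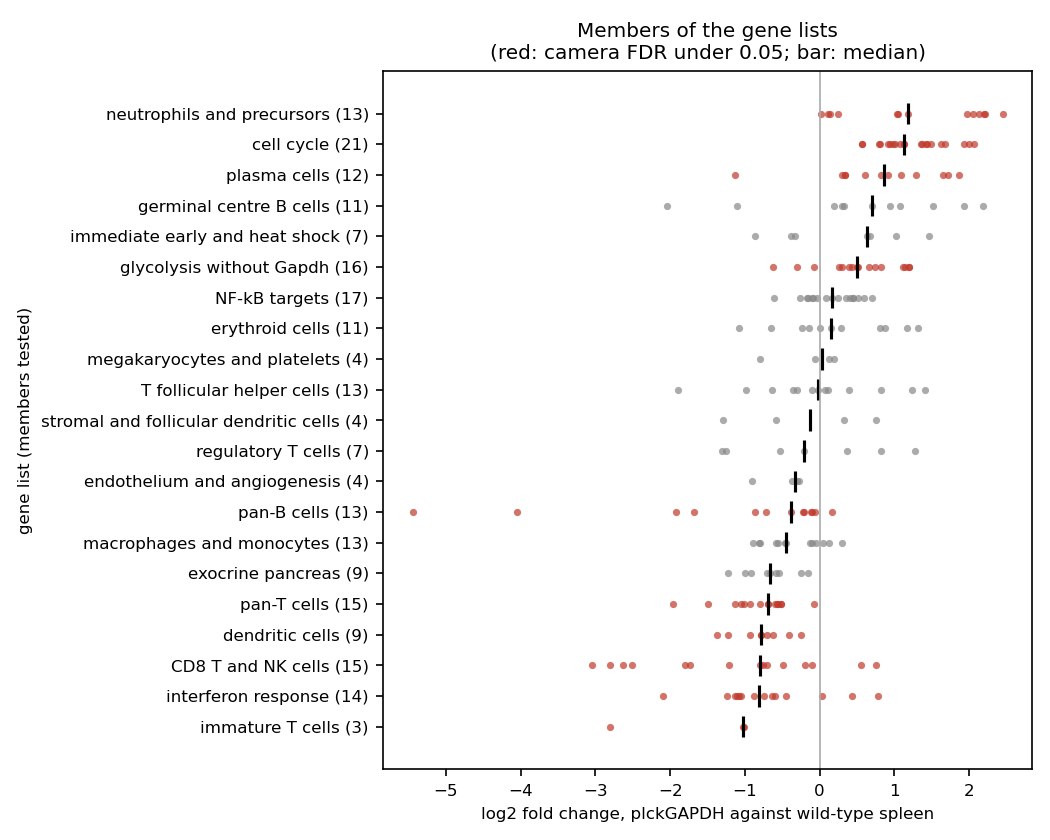
Log2 fold change of each tested member (points) and median (bar) of 21 gene lists, plckGAPDH against wild-type spleen, with lists called by camera at the preset correlation in red. Cell cycle genes lay between 0.56 and 2.07, and the pan-B list held Cr2 at -5.44 and Fcer2a at -4.05.

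The comparison of plckGAPDH lymph nodes with plckGAPDH spleens asks how tissue changes expression within transgenic mice; wild-type lymph nodes were not analysed here, so genotype was not compared in that tissue. The lymph nodes differed in their receptor genes, with a mean overlap of V gene shares of 16.4%. Their titles also differ, with MES for animal 455 and LN for animal 508. A difference of site between the nodes could therefore not be told apart from a difference between the animals. Lymph node 455 held 11647 FPKM of Ighe, of class IgE. Ighe was at most 30.3 in wild-type spleens, 4.41 to 413 in plckGAPDH spleens and 317 in lymph node 508. It made 88.2% of the heavy-chain constant FPKM of lymph node 455, which also held 22054 FPKM of Igkc. Ighv1-12 made 69.9% of its heavy-chain V genes, Igkv4-61 24.8% of its kappa V genes, Trbv2 61.2% of its Trbv genes and Trav12n-3 31.8% of its Trav genes. Lymph node 508 resembled the spleen of the same animal, with Ighg2c at 27891 FPKM, Iglc1 at 53162 FPKM, Ighv1-54 at 33.8% and Igkv4-63 at 36.0%, and with Trav21-dv12 at 45.1% and Trbv3 at 34.1%. Its Trav share rested on only 179 estimated fragments. Only 2 of 13682 genes were called with limma, while 1546 had an unadjusted p under 0.05. That unadjusted count was 451 with median-of-ratios scaling, 367 with scaling to protein-coding genes, 4089 without spleen 508, 723 without spleen 547, 611 without the unnumbered spleen and 497 without lymph node 508. The 2 called genes are small RNA genes. Gm27605 (limma FDR 0.00817) was listed at 0 in all 7 spleens and at 5.77 and 13.1 FPKM in the lymph nodes. Gm25534 (limma FDR 0.0413) was listed at 0 in both lymph nodes and at 16.9 to 85.5 FPKM in plckGAPDH spleens. Both genes are shorter than the estimated mean fragment length, which was 160 bases in both lymph nodes, so their FPKM are uncertain. Without either lymph node, the lone one left is assumed to vary like the other groups. Both genes fall outside the naming rule and were named after their values were seen. The median gene was lower by -0.59 on the log2 scale in lymph nodes, and by -0.01 with median-of-ratios scaling, where 1 gene, a higher one, was called. Counts with limma were 0 without lymph node 455, where 919 genes had an unadjusted p under 0.05, 28 without lymph node 508, 24 without spleen 508, 4 without spleen 547 and 1 without spleen 343.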

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

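The tests below were chosen only after the result was seen, except the test of clone expansion. In 4 of 57 results looked at (7.02%), 1 of the 4 plckGAPDH spleens stood apart from the other 3 by a share of the group's range above the 95% limit of Dixon's test, and chance marks about 1 in 20 groups. Cd55 was highest in spleen 547 (ratio 0.909; 4.19 against 2.75 to 2.88 on the log2 scale). Cxcr5 was lowest in spleen 508 (0.859; 1.97 against 4.23 to 4.61). Amy2a5 was highest in spleen 343 (0.901; 3.53 against 0.16 to 0.50), and Ighe was highest in spleen 508 (0.832; 8.69 against 2.44 to 3.49).

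Of the 35 splits of the 7 spleens into 3 and 4, only 1, the real one, called as many as 181 genes, and the highest of the others called 14. The real split thus stood apart, but 1 of 35 is the smallest share these splits allow, and chance cannot be excluded. Called V genes can fall together, so the count largely restates their fall. Of the 181 called genes, 125 were receptor segments, and with receptor genes left out 0 of 12360 genes were called. The count thus says little about genes outside the receptor loci. For lists, 22 of the 35 splits called at least as many as the real split, which called 10, and the highest other called 14. Chance cannot be excluded for the count of lists, so the list results carry little weight.

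The first pattern is the fall of immunoglobulin V genes in plckGAPDH spleens. Fewer B cells with an unchanged repertoire would lower the sum of V genes as much as single V genes. But the sum of all heavy-chain and kappa V genes differed by -0.69 (SE 0.49) and the median tested gene by -3.14. The median covers only V genes at 1 FPKM in 3 spleens, a filter that genes high only in wild-type spleens can pass. Without a filter the medians were -1.96 for heavy-chain and -2.44 for kappa V genes, so the size of the gap depends on the filter. That sum leaves out lambda V genes, of which Iglv1 alone held 42593 FPKM in spleen 508, against 99.0 to 338 in wild-type spleens. The value of -0.69 is therefore not the difference of all V genes. Scaling was argued against by a median of -3.09 with median-of-ratios scaling. Expansion of few B cell clones is a candidate explanation that the data do not contradict (exact permutation p 0.0286, the smallest that 35 splits allow, and 0.0571 adjusted, which did not pass). That p comes from the same V gene values as the fall, so it largely restates the pattern and is no separate support. Shared reads among similar V genes and the age of the mice stay open.

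The second pattern is the unnumbered spleen; the title of spleen 331 has no column of its own, but nothing in the table links the 2. Its column label holds the letter B and the titles of spleens 343 and 547 the letter A, without a stated meaning. The unnumbered spleen could thus be a second piece of spleen 343 or 547. With the same expansions, its V gene shares would then overlap as in spleen and lymph node of animal 508, by 62.6% to 79.1%. The highest overlap over the families was 27.7% with spleen 343, through Igkv5-39, and 26.2% with spleen 547. Only 1 pair of tissues served as reference, so a second piece with other expansions stays open, in which case the 4 plckGAPDH spleens would come from 3 animals. No biological explanation was tested.

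The third pattern is Ighv12-3 (82.4 FPKM) and Igkv4-91 (190 FPKM) in lymph node 508, the V genes that dominate spleen 547. Carry-over from spleen 547 would bring its other abundant genes at 2.46% to 3.52%, but 16 such genes had a median of 0.982%, and 15 of them lay below the expected level, the exception being Saa3. Reads of Igkv4-63 counted on Igkv4-91 would keep their ratio, but Igkv4-91 was 40.4% of Igkv4-63 in lymph node 508 and 1.33% in spleen 508. No biological explanation was tested.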

How the results depend on the processing

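The alternatives named below as added were chosen only after the data had been seen: a pseudocount of 0.1, a filter of 5 FPKM, sample quality weights, scaling to protein-coding genes, wild-type spleens 4 and 5 both left out, and no minimum of V gene fragments. The weighted fit put a weight of 24.8 on wild-type spleen 1 and at most 2.04 on any other spleen, with a warning that the weights had not converged. Leaving out wild-type spleens 4 and 5 leaves 1 wild-type spleen, which limma assumes to vary like the plckGAPDH spleens. Not run were the DESeq2 Wald test and limma-voom with or without weights or a correlation within animals, because they need counts, and filters on counts, which were replaced by filters on FPKM. The planned fit without the animal left over among the titles was run as leaving out the unnumbered spleen. No paired analysis was possible because only animal 508 gave both tissues. A correlation within animals was tried in limma on the log2 values, a choice made after the data had been seen, with the unnumbered spleen as its own animal. It gave a correlation for 0 of 13682 genes, since limma needs more repeated animals than 9 samples of 8 animals hold. The lymph node p-values therefore ignore that animal 508 gave 2 samples.

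The 181 genes called with limma between the spleens became 74 without a filter (1 higher, 73 lower), 1863 with sample quality weights (891 higher, 972 lower), 12 without wild-type spleens 4 and 5 (3 higher, 9 lower) and 0 with receptor genes left out (0 higher, 0 lower, 947 at an unadjusted p under 0.05). The higher genes were 9 with median-of-ratios scaling, 14 with a pseudocount of 0.1 and 11 with scaling to protein-coding genes. With 1 library left out the total ran from 72 to 265, the higher genes from 5 to 81 and the lower genes from 67 to 189. For lymph node against spleen, the 2 calls became 1 with median-of-ratios scaling, 5 without a filter, 8 with only the plckGAPDH samples, 5 with a pseudocount of 0.1, 1 with scaling to protein-coding genes, and 0 to 28 with 1 library left out. Unadjusted p under 0.05 numbered 1116 between the spleens, and 1960 without a filter, 630 with a filter of 5 FPKM, 3902 with sample quality weights and 310 without wild-type spleens 4 and 5. They numbered 1546 for lymph node against spleen, and 451 with median-of-ratios scaling, 367 with scaling to protein-coding genes and 497 to 4089 with 1 library left out. Heavy-chain V genes that fell numbered 58, and 28 to 67 with 1 library left out; kappa V genes 61, and 34 to 66. The cause of these differences was not tested.

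The 10 called lists became 0 with an estimated correlation and 0 with fry. The direction of the camera test turned in 34 of 332 results of lists under alternatives, 254 kept direction and call, 30 lost the call and 14 gained it. Without wild-type spleens 4 and 5 it turned for macrophages (median 0.61), neutrophils (-1.37), megakaryocytes (0.70), interferon genes (0.016), follicular helper T cells (0.29) and regulatory T cells (0.38). With sample quality weights it turned for follicular helper T cells (1.02), pan-T cells (0.22), neutrophils (-1.31), interferon genes (0.36), macrophages (0.69), regulatory T cells (0.52), megakaryocytes (0.83) and stroma (0.40). With all 6 plckGAPDH samples it turned for follicular helper T cells (-0.27), NF-kB targets (-0.33), stroma (-0.059) and pancreas (-0.031), where the median and the test can differ in sign. For megakaryocytes it also turned with median-of-ratios scaling (0.039), scaling to protein-coding genes (0.16) and a pseudocount of 0.1 (0.43).

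With 1 library left out, directions turned in lists whose medians ran from -0.68 to 0.56 (follicular helper T cells), -1.05 to 0.57 (regulatory T cells), -0.99 to 0.54 (macrophages), -1.02 to 2.69 (erythroid cells), -0.72 to 0.92 (megakaryocytes), -0.42 to 0.25 (stroma), -0.029 to 0.89 (immediate early genes) and 0.32 to 1.40 (plasma cells, lowest without spleen 508). Without a turn of direction they ran from -0.12 to 0.49 for NF-kB targets and 0.37 to 1.06 for germinal centre B cells. The pancreas list had too few members tested to give a value in some of these fits.

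With all 6 plckGAPDH samples against the wild-type spleens, the differences in effective number passed the adjusted exact permutation test: -39.4 for Ighv, -37.2 for Igkv, -47.0 for Trav and -9.43 for Trbv. That test counts both tissues of animal 508, except for Trav. The other 44 of 48 results stayed on the same side of the threshold, and with 1 library left out no exact p under 0.0667 was possible. Of 649 results of the 37 named genes, 509 kept direction and call, 122 lost the call, 13 gained it and 5 turned. Those were Lcn2 in spleen with sample quality weights (-1.35) and without wild-type spleens 4 and 5 (-1.49), and Ppbp in spleen with these (0.90 and 0.79) and with 1 library left out (-1.75 to 0.94); neither gene was called in any of them. Gapdh gained it with sample quality weights (1.29).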

Other observations

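Libraries of plckGAPDH mice differed from each other in genes of lymphocytes. The unnumbered spleen held the highest FPKM of the T cell genes Pdcd1 (96.3, against 1.64 to 28.0 in wild-type spleens), Icos (82.6) and Batf (222), with Cd4 at 82.9, beside Trbv20 at 75.8% of Trbv genes. Of the 14 genes of the follicular helper list, 11 lay above every wild-type spleen there, and Cxcr5 lay below (22.9, against 34.3 to 71.1). General T cell genes were also high there: 8 of 15 pan-T genes lay above every wild-type spleen, against 0 in each other plckGAPDH spleen, with Cd3e at 79.2 and Cd247 at 108. Of the regulatory T cell genes, 5 of 9 lay above every wild-type spleen, while Foxp3 was at 0.690, against 2.04 to 4.78 in wild-type spleens. Spleen 547 held 146 FPKM of Mki67 and 4.32 of Cd4. Both tissues of animal 508 held high Fos (59.6 and 29.6, at most 3.99 elsewhere), and these and lymph node 455 held Vegfa at 16.7, 11.3 and 10.6, against at most 1.06 elsewhere.

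A hypothesis is that T and B cell clones expanded side by side in some of these mice. The exact permutation p for Ighv was 0.0286, and 0.0571 adjusted, which did not pass the threshold. The T cell receptor families gave weaker values: an exact p of 0.114 for Trbv, and for Trav 0.0571 (0.0762 adjusted), which was 0.143 with fragments thinned to equal totals. Such expansions may be tumours, reactive plasma cells or B cells helped by expanded T cells; bulk FPKM of V genes cannot tell these apart, and no receptor sequences were analysed here. The series title speaks of a T cell lymphoma. Receptor sequencing of the same RNA would test the hypothesis, which predicts few shared rearrangements per animal. Trbv use was most concentrated in the unnumbered spleen (effective number 2.88) and Trav use in spleen 508 (4.71), and spleen 547 had a Trbv effective number of 16.7, near the 16.8 of wild-type spleen 4, beside 98.8% Ighv12-3.

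Wild-type spleen 5 was the only library with RNA of the Y chromosome, and it differed from wild-type spleens 1 and 4 in blood RNA. Sex was therefore not balanced between the groups. Leaving that spleen out compares only libraries without Y chromosome RNA, a test chosen after the result was seen. Immunoglobulin V genes stayed lower, with a median of -3.05 (SE 0.286), which argues against sex as the whole cause of their fall. Of the 72 genes called with limma there, 70 were among the 181 called with all spleens, and 64 were receptor segments. Only 5 higher and 3 lower genes outside the receptor loci were called, and 3 of the 17 called named genes stayed called. Of the 17, 0 turned in direction. Each gene outside the receptor loci called with all spleens showed no overlap between the wild-type and the plckGAPDH spleens. Leaving out spleen 5 cannot create an overlap, so the lack of overlap does not test sex or the blood RNA of spleen 5. For the lost calls, sex, that blood RNA and the smaller number of spleens stay open.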
